A study of Rattus norvegicus with 24 samples.

How the data were processed

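Liver RNA of rats (Rattus norvegicus) was measured on 24 oligonucleotide arrays. The sample titles were read as a day (1, 2, 4 or 7), a letter and a number. The series title names burn injury and some descriptions name a sham control, so the letter b was read as burn and s as sham. This gave 8 groups of 3 arrays. The descriptions of burn day 1 replicates 1 and 3 and of burn day 2 replicate 1 speak of a sham control, against their titles. The titles were followed, and all comparisons were repeated without those 3 arrays. That repeat leaves 1 burn array on day 1, so it cannot test the day 1 result. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. What the sham rats underwent and how the burns were made are not given in the sources used here.

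The deposited values are linear array intensity, 1 signal per probe set, for 15923 probe sets on each array. The software behind the signal is not given in the sources used here. Every column had a mean of 500.2 after the lowest and highest 2% were left out, so the deposited intensity had been scaled per array. No value lay below 0, and median intensity ran from 174 to 233. Values were taken to log2(signal + 16). By a rule fixed before the data were examined, quantile normalization was applied if array medians differed by more than 0.25 or interquartile ranges by more than 20%. They differed by 0.39 (log2) and 25.1%, and the arrays were quantile-normalized. Differences are therefore on the log2(signal + 16) scale and understate changes of dim probe sets. The number of arrays limits the precision.

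The names and the values of the table did not belong together. Over all 15923 rows, arrays of day 1 correlated with each other at 0.936 to 0.957, and arrays of days 2, 4 and 7 at 0.941 to 0.971. Arrays of day 1 correlated with the other 18 at only 0.028 to 0.043. In neither set did the values match the probe set names row by row. For 1868 pairs of probe sets listed under the same gene symbol, the mean levels correlated at 0.0453 on day 1 and -0.0483 on the other days. The 2 rows listed under albumin (Alb), the most abundant secreted liver protein, stood at 5.20 and 8.71 (log2, days 2, 4 and 7), the latter at percentile 69.3, and at 10.88 and 10.99 on day 1 (percentiles 92.6 and 93.1). The row listed under transthyretin (Ttr), another secreted liver protein, stood at 12.89 on day 1 (percentile 98.3) and at 8.20 on the other days (percentile 59.4). Listed hepatocyte markers had a median percentile of 55.5 on days 2, 4 and 7, where 95% of 10000 random lists lay between 26.5 and 73.5. On day 1 it was 81.7, above the 27.0 to 73.0 of random lists but inside the 39.0 to 85.0 of lists drawn within 200 rows of the same places, since bright rows of day 1 stood together (correlation of neighbouring rows 0.298, against 0.0141 on the other days). Listed ribosomal proteins stood at 41.3 on day 1 and 44.8 on the other days. A loose relation between names and places on day 1 is thus not excluded, but the names could not be relied on for single rows.

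Rows named as array controls kept their known pattern on days 2, 4 and 7. On day 1 that pattern stood in the first 57 rows of the table: 27 control values correlated at 0.997 with the named controls of the other days, against -0.152 for the rows carrying the names. No order that restored the names was found. The best of 15923 circular shifts gave a correlation of 0.0372 between day 1 and the other days, and 18 sorted orders gave at most 0.0376 in size. Of these orders, 4 that sort by gene raised the correlation of same-gene pairs on day 1 to between 0.239 and 0.301, and not on the other days. They put all such pairs (100%) on neighbouring values, and neighbouring values of day 1 correlated at 0.298 as listed, so this was not taken for a match. More orders, shifts and local alignments than these were looked at without a match. All of this was examined after the data were seen.

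The annotation lists 1 gene symbol for 12789 probe sets, several for 312 and none for 2822. Because of the mismatch it was not used to name genes. Named are only the control transcripts Gapdh, Actb and Hk1 on days 2, 4 and 7. All 43 gene lists fixed before the data were examined, and the genes meant to be named in any case, could not be tested under those names.

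Within each set of arrays a row holds 1 transcript, so burn could be compared with sham. The design fixed beforehand was 1 limma fit of all 24 arrays. It was departed from before any fit was run: day 1 (6 arrays, 4 residual degrees of freedom) and days 2, 4 and 7 (18 arrays, 12 residual degrees of freedom) were fitted apart, with 1 mean per group, lmFit and eBayes. Contrasts were burn minus sham on each day and the mean of days 2, 4 and 7. F tests asked whether the burn effect differed between days 2, 4 and 7 and whether these days differed among sham arrays. The mean of the 4 days, and F tests that include day 1, were not run because they would combine different transcripts. Rows named as controls (days 2, 4 and 7) or the first 57 rows (day 1) were left out, and 15866 rows were tested. P-values were adjusted by the Benjamini-Hochberg method, and a row is said to be called at an adjusted p under 0.05. All p are two-sided.

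The fixed rule for naming took, per day, the 8 largest rises and falls among called rows with no overlap between burn and sham, and for the mean the 12 largest with 1 direction on every day. It was kept apart from its need for a gene symbol and its use of day 1. The listed identifiers of single rows are not printed, since they do not say which transcript was measured.

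For the control transcripts, level was the mean of the 3', middle and 5' probe sets, and the 3' over 5' difference of log2 signals described RNA quality. Burn and sham were compared by exact permutation within days, and 6 such tests were adjusted together.

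The fits were tested on simulated data with the real row means and shrunken variances and 200 changed rows. Noise was normal and drawn independently, so errors shared between rows were not simulated. Shrunken variances also differ less between rows than the real ones. The recovery below may therefore be too high for the real data. On day 1, 16 of 100 rows changed by 1 (log2) and 81 of 100 changed by 2 were called. In the real day 1 data, 13 rows were at least 4-fold higher and 10 at least 4-fold lower without overlap, and 0 were called. In the simulated data 56 and 92 were called on day 7, and 79 and 99 for the mean of days 2, 4 and 7. The F test for a burn effect that differs between days recovered 26 and 82, and 12 of its 120 calls were false (10%). With all 24 arrays in 1 fit, 168 of 316 calls on simulated day 1 data were false (53.2%), against 4 of 101 (3.96%) for day 1 alone.

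Alternatives were values as deposited, median scaling, pseudocounts of 1 and 64, leaving out the dimmest 33.3% of rows, an intensity trend with robust variance, array weights, replicate numbers as blocks, each array left out in turn, single-day fits, all sham arrays of days 2, 4 and 7 as control, and a log2 threshold of 1. Chosen after the data were seen were the separate fits, the fit of all arrays as an alternative, and the Actb 3' over 5' ratio as a covariate. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.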

Results

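The series measured whole-liver RNA of rats on 24 arrays after burn injury or sham treatment, with 3 burn and 3 sham arrays on each of days 1, 2, 4 and 7. The comparisons ask how the liver transcriptome of burned rats differed from that of sham rats on each day. Median log2 signal was 7.82 ± 0.08 (SD, n = 12) on burn arrays and 7.81 ± 0.11 (SD, n = 12) on sham arrays, a difference of 0.02 (permutation p = 0.63, all relabellings within days). On day 7, not tested alone, it was 7.79 ± 0.07 on burn and 7.66 ± 0.10 on sham arrays (SD, n = 3 each), with interquartile ranges of 2.46 and 2.62, before normalization.

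The probe set names did not match the values, and the rows of day 1 did not correspond to those of the other days. Rows are therefore described without gene names, and no row of day 1 is set against a row of a later day. Only the control transcripts of days 2, 4 and 7 are named.

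**Figure D1:**
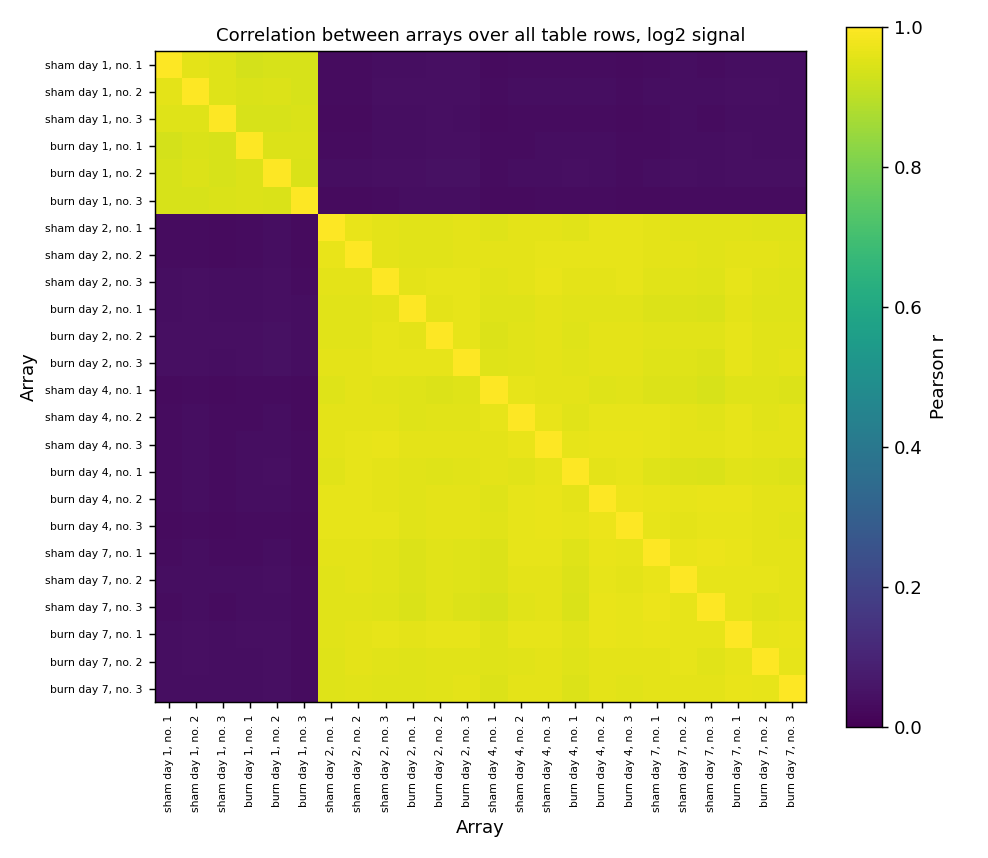
Pearson correlation between all 24 arrays over all rows of the table (log2 signal), ordered by day, sham before burn. The 6 arrays of day 1 correlated with each other at 0.936 to 0.957 and with the other 18 at 0.028 to 0.043.

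On day 1, the row with the largest rise without overlap between arrays stood at 5.51 ± 1.00 (SD, n = 3) log2 units in sham and 11.57 ± 0.90 (SD, n = 3) in burn, a difference of 6.06 ± 0.62 (SE) with a limma adjusted p of 0.0826. Its sham values were dim, and the difference was 6.84 with a pseudocount of 1 and 4.99 with one of 64. The next largest differences were 3.20 ± 0.35 and 2.98 ± 0.38 (SE) upward. The largest such differences in the other direction were -2.87 ± 0.25 and -2.41 ± 0.22 (SE), each with a limma adjusted p of 0.0606. Their sizes were -3.76 and -3.02 with a pseudocount of 1, and -1.80 and -1.54 with one of 64. A very bright row stood at 12.60 ± 0.04 (SD, n = 3) in sham and 14.25 ± 0.04 (SD, n = 3) in burn liver, with the same limma adjusted p of 0.0606. These rows were picked after their values were seen.

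With limma, 0 rows of day 1 were called at an adjusted p under 0.05, the smallest being 0.0606, while 72 lay under 0.1. At an unadjusted p under 0.05 there were 1778 rows (853 higher and 925 lower in burn), where chance alone gives 793. In 18.7% of rows the 3 burn and 3 sham arrays did not overlap, against 10% by chance, and among these 163 rows were at least 2-fold higher and 210 at least 2-fold lower. The count of calls moved with the setting: 222 rows were called with an intensity trend and robust variance, 59 without the dimmest 33.3% of rows and 55 with a pseudocount of 64. It was 724 in the fit of all 24 arrays, where simulated data gave 53.2% false calls.

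On days 2, 4 and 7 a pair of rows had larger rises than any other on the mean of the days. They were higher in burn by 3.67 ± 0.56 (SE) and 3.48 ± 0.51 (SE) log2 units (limma adjusted p = 0.0164 and 0.0139), with all 9 burn arrays above the sham mean of their day. Both calls held under 28 of 29 alternatives and ended with the Actb 3' over 5' ratio as a covariate (limma adjusted p = 0.493 and 0.471; range over all alternatives 0.00079 to 0.493 and 0.000726 to 0.471). The first stood at 10.83 ± 0.84 (SD, n = 3) in burn and 5.76 ± 2.28 (SD, n = 3) in sham on day 2, at 7.17 ± 0.76 and 4.93 ± 0.22 on day 4, and at 9.61 ± 0.75 and 5.92 ± 1.84 on day 7. The burn effect on this row was not shown to differ between days (limma adjusted p = 0.669). In the first row 7 of 9 sham arrays were dim, at 4.38 to 5.08, and the size moved with the pseudocount: over all alternatives it ran from 2.67 (pseudocount 64) to 4.58 (pseudocount 1) in the first row and from 2.58 to 4.19 in the second, with the same settings at the ends. The wide sham spread came from sham day 2 replicate 3 and sham day 7 replicate 3, which read 8.38 and 8.03 in the first row and 8.25 and 8.15 in the second.

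The largest fall on the mean of the days, -1.96 ± 0.39 (SE), was not called (limma adjusted p = 0.0636). Among called rows with the same direction on every day, the largest falls were -1.69 ± 0.30 (SE) and -1.28 ± 0.24 (SE) (limma adjusted p = 0.0384 and 0.0481). In the first, 9 of 9 burn arrays lay below the sham mean of their day, in the second 8 of 9. Neither call was stable: they ended under 22 and 21 of 28 alternatives, with limma adjusted p from 0.00103 to 0.494 and from 0.0166 to 0.471, although the direction stayed. Their sizes ran from -2.08 (pseudocount 1) to -1.11 (pseudocount 64) and from -2.26 to -0.61, with the same settings at the ends.

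**Figure D2:**
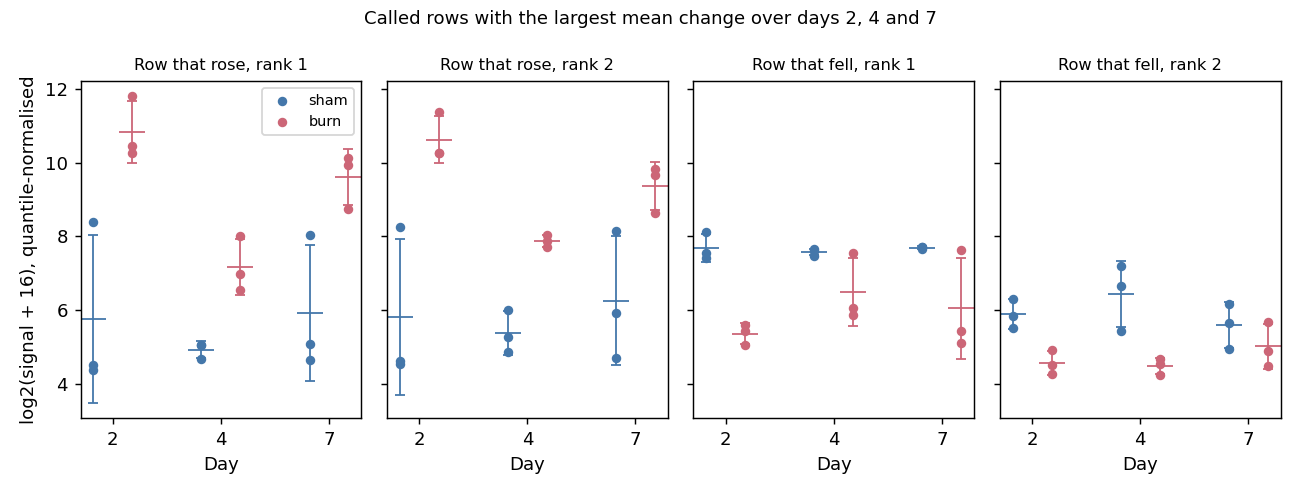
Log2(signal + 16) after quantile normalization on each array of days 2, 4 and 7, for the 2 largest rises and the 2 largest falls among rows called on the mean of these days with the same direction on each. Points are arrays, horizontal marks are means and bars are ± SD (n = 3). The row of rank 1 among rises averaged 10.83 in burn and 5.76 in sham on day 2.

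Over the mean of days 2, 4 and 7, limma called 34 rows, 18 higher and 16 lower in burn liver. On values as deposited there were 21 calls, 15 of them higher, and with median scaling 17, 11 of them higher. At an unadjusted p under 0.05 there were 1624 rows, against 793 by chance. Other splits of these arrays within days gave a median of 755 such rows and reached 1403. Leaving out single arrays moved the count between 11 (without sham day 2 replicate 1) and 49 (without burn day 7 replicate 2).

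By single day, limma called 0 rows on day 2, 0 on day 4 and 8 on day 7, with 1400, 1482 and 1563 rows at an unadjusted p under 0.05. The smallest adjusted p of limma were 0.0926, 0.0884 and 0.00569. Burn and sham arrays did not overlap in 13.2%, 14.8% and 15.8% of rows, against 10% by chance. The 8 rows of day 7 were 4 higher and 4 lower in burn. The largest rise among them was 1.37 ± 0.19 (SE), and the largest fall -1.95 ± 0.31 (SE), with limma adjusted p of 0.0202 and 0.0366. That rise was of a dim row, in which the burn arrays of day 7 stood apart. They averaged 6.39, against 5.25 and 5.36 in burn on days 2 and 4 and 4.99 to 5.05 in sham. In that fall the sham arrays of day 7 stood apart instead: they averaged 7.71, against 5.88 and 5.75 in sham on days 2 and 4, while burn averaged 6.30, 5.98 and 5.76 on the 3 days. The same held for another fall, also of a dim row (sham 5.29, 5.27 and 6.36, burn 5.21, 5.28 and 5.22). In a rise, sham averaged 7.08, 7.28 and 6.28 and burn 6.65, 6.92 and 7.18, so burn was the lower on days 2 and 4. Which arm moved was not tested for single rows. With an intensity trend and robust variance the counts were 32, 5 and 56. The count on day 7 ran from 2 without burn day 7 replicate 3 to 65 without sham day 7 replicate 2, and was 0 when the 6 arrays of that day were fitted alone.

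**Figure D3:**
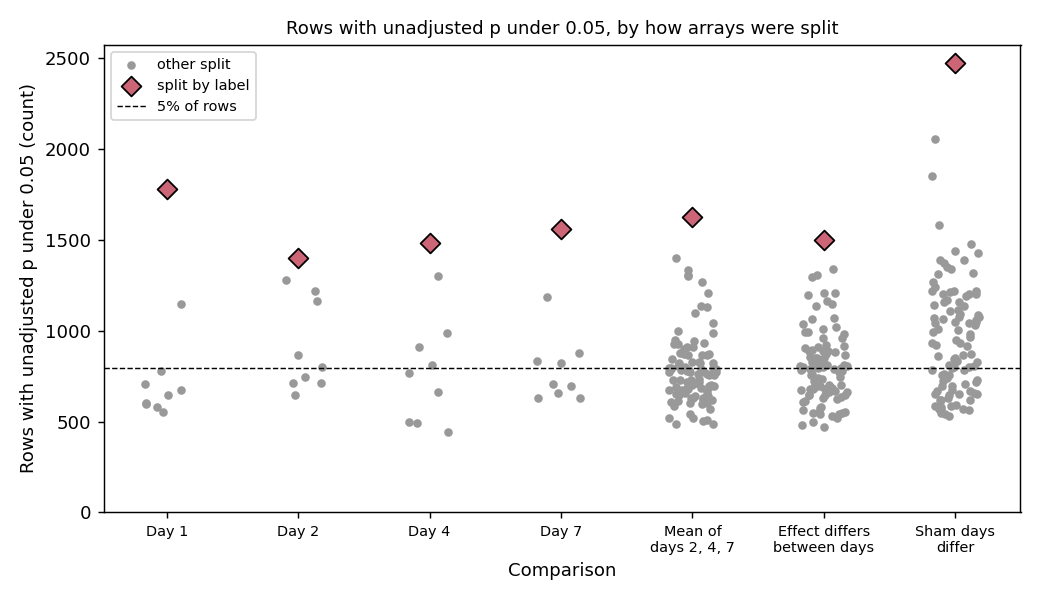
Number of rows with an unadjusted limma p under 0.05 (vertical axis) for each comparison (horizontal axis), with arrays split by label (diamonds) and split in other ways (grey points). The dashed line is 5% of the rows, 793. Split by label, day 1 gave 1778 rows and at most 1146 in another split.

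Whether the burn effect differed between days 2, 4 and 7 was asked by an F test in limma. It called 0 rows, with a smallest adjusted p of 0.0771 and 1499 rows at an unadjusted p under 0.05. That 0 was not stable: 11 rows were called with an intensity trend and robust variance and 8 with array weights. Leaving out single arrays gave up to 19 (without sham day 7 replicate 2). Among sham arrays alone, 8 rows differed between the 3 days, and 2474 had an unadjusted p under 0.05. The 8 calls were not stable: leaving out single arrays gave 1 (without burn day 4 replicate 2 or sham day 4 replicate 2) to 25 (without sham day 7 replicate 2), and a pseudocount of 1 gave 2.

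The burn effects of days 2 and 7 correlated across rows at 0.187 (Spearman 0.141), each day against its own sham arrays. Days 2 and 4 gave 0.0141 and days 4 and 7 gave -0.0472. Rows are not independent replicates. Of 269 rows with an unadjusted p under 0.05 on both days 2 and 7 (138 expected of independent lists), 148 were higher on both, 81 lower on both and 40 opposite. For days 4 and 7 there were 236 such rows (146 expected), 146 of them opposite. Days 2 and 4 shared 187 (131 expected), 88 of them opposite. Each row has the same SE on every day of this fit, so rows can pass on both days without a shared effect. The excess over independent lists is therefore not read as agreement between days. Of 100 pairs of splits of days 4 and 7, 41, the real one among them, gave a correlation at least as large in size. For days 2 and 4 it was 70 of 100, and for days 2 and 7 only the real one.

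**Figure D4:**
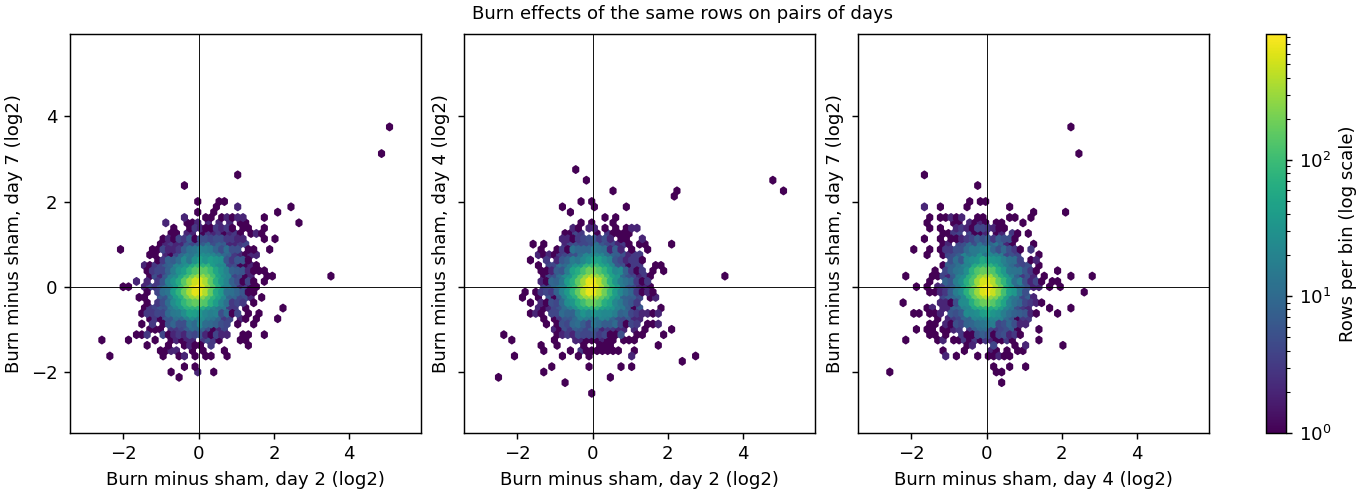
Burn minus sham (log2) of the same rows on pairs of days, as counts of rows per bin on a log colour scale. Days 2 and 7 correlated at 0.187, days 2 and 4 at 0.0141, and days 4 and 7 at -0.0472.

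Gapdh, a glycolytic enzyme, averaged 13.13 ± 0.10 (SD, n = 9) in burn and 13.08 ± 0.10 (SD, n = 9) in sham liver over days 2, 4 and 7 (exact permutation p = 0.377, adjusted 0.655). Actb, cytoskeletal beta-actin, averaged 12.78 ± 0.28 and 12.71 ± 0.27 (SD, n = 9 each; exact permutation p = 0.546, adjusted 0.655). Hk1, hexokinase 1, averaged 5.98 ± 0.39 and 5.89 ± 0.50 (SD, n = 9 each; exact permutation p = 0.694, adjusted 0.694). None of these differences passed the test. By day, Actb in burn minus sham was 0.14, -0.39 and 0.45 on days 2, 4 and 7, where 3 arrays against 3 allow no exact p below 0.1.

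The 3' over 5' ratio of Actb was lower on burn arrays, 0.49 ± 0.27 against 0.83 ± 0.33 (log2; SD, n = 9 each; exact permutation p = 0.0192), but did not pass adjustment over 6 tests (0.115). The difference was -0.39 on day 2, 0.09 on day 4 and -0.73 on day 7. For Gapdh it was -0.16, 0.12 and -0.46 (all days, exact permutation p = 0.0988, adjusted 0.296). For Hk1, a dim transcript, it was 0.37, -0.11 and -0.91 (all days -0.22, exact permutation p = 0.517, adjusted 0.655). The ratios of Actb and Gapdh, but not that of Hk1, were lower in burn on both days 2 and 7, the days whose burn effects correlated. With the Actb ratio as a covariate, an alternative chosen after the data were seen, limma called 0 rows on day 7 and 0 on the mean of the days. All 8 rows of day 7 kept their direction, their median size going from 1.05 to 0.94 and their median SE from 0.14 to 0.23. All 34 rows called on the mean kept theirs, their median size going from 0.67 to 0.59 and their median SE from 0.11 to 0.16.

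**Figure D5:**
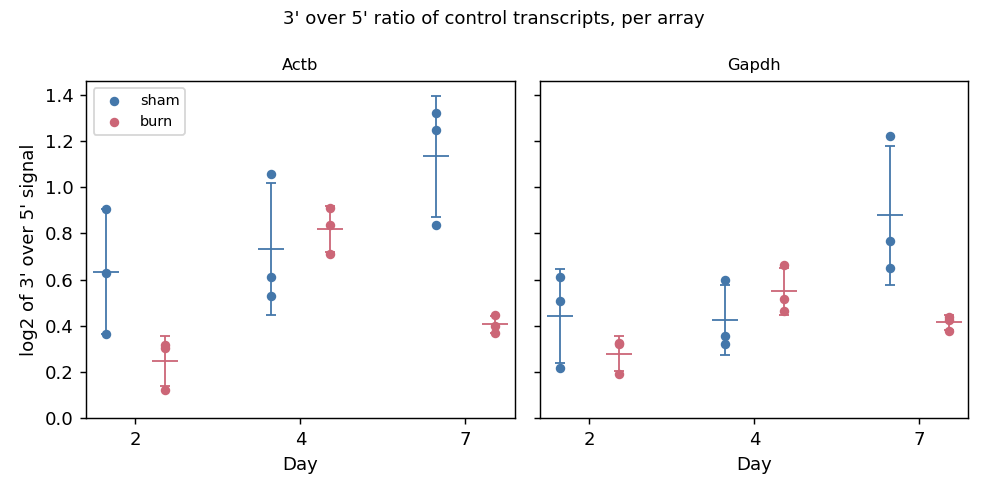
Log2 ratio of 3' over 5' signal of Actb and Gapdh on each array (points) by day, with mean (horizontal mark) and ± SD (bar, n = 3). On day 7 Actb averaged 1.13 on sham and 0.41 on burn arrays, and on day 4 it averaged 0.73 and 0.82.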

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

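For the control transcripts, burn arrays all lay on 1 side of the sham mean on 1 day and all on the other side on another day. These differences between days were not tested. The level of Actb was 0.14 higher in burn on day 2, -0.39 on day 4 and 0.45 on day 7 (burn minus sham, log2). Its direction on each day was the same with values as deposited and with median scaling, but the size moved. It was 0.227 and 0.26 there on day 2, and 0.369 and 0.245 on day 7. The level of Hk1 was 0.56 on day 2, -0.49 on day 4 and 0.23 on day 7, again with the same signs under both other scalings. The level of Gapdh was -0.078 on day 2 and 0.22 on day 7, and its sign on day 2 flipped to 0.0279 with median scaling, where day 7 was only 0.0434. The 3' over 5' ratio of Gapdh was -0.16 on day 2, 0.12 on day 4 and -0.46 on day 7.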

How the results depend on the processing

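Chosen after the data were seen were the fit of all 24 arrays, as an alternative to separate fits, and the ratio covariate. Counts below are rows called by limma on days 1, 2, 4 and 7 and on the mean of days 2, 4 and 7, against 0, 0, 0, 8 and 34, then rows whose burn effect differed between days (0) and rows that differed between sham days (8). Values as deposited gave 4 on day 1, 3 on day 4, 21 on the mean and 24 between sham days. Median scaling gave 3 on day 1, 5 on day 7 and 17 on the mean. The share of higher calls on the mean was 52.9%, against 71.4% as deposited and 64.7% with median scaling; on day 7, 4 of 8 calls were higher, against 7 of 12 as deposited, 1 of 5 with median scaling, 15 of 21 with a pseudocount of 64 and 40 of 56 with intensity trend and robust variance. A pseudocount of 1 gave 21 on the mean and 2 between sham days. A pseudocount of 64 gave 55 on day 1, 7 on day 2, 21 on day 7 and 20 between sham days. Without the dimmest 33.3% of rows there were 59, 13, 2, 4 and 53, and 25 between sham days. Intensity trend with robust variance gave 222, 32, 5, 56 and 88, then 11 and 49. Array weights gave 4 on day 1, 1 on day 4, 39 on day 7, 8 for a differing effect and 21 between sham days. Without the 3 arrays with conflicting descriptions there were 13 on day 7 and 5 between sham days. Day 1 then had only 1 burn array, and its count is not read. Single-day fits gave 0 on day 7. All sham arrays as control gave 115, 6 and 43 on days 2, 4 and 7. That control joins sham arrays of other days, so differences between days enter these counts. A log2 threshold of 1 left 5 on day 7 and 8 on the mean. The fit of all arrays gave 724, 19, 4 and 25 on days 1, 2, 4 and 7. The ratio covariate left 0 on day 7 and 0 on the mean (smallest adjusted p 0.45 and 0.471), with median sizes going from 1.05 to 0.94 and from 0.67 to 0.59 and median SE from 0.14 to 0.23 and from 0.11 to 0.16. The causes were not tested.

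Leaving out each array in turn gave 0 to 0 on day 1, 0 to 20 on day 2, 0 to 6 on day 4, 2 to 65 on day 7, 11 to 49 on the mean, 0 to 19 for a differing effect and 1 to 25 between sham days. The highest came without sham day 2 replicate 3 (day 2), burn day 4 replicate 1 (day 4), sham day 7 replicate 2 (day 7, differing effect and sham days) and burn day 7 replicate 2 (mean). The mean fell to 11 without sham day 2 replicate 1, 12 without sham day 4 replicate 2, 17 without sham day 4 replicate 1, 18 without burn day 4 replicate 2 and 22 without burn day 2 replicate 3. On day 7 the count was 2, 4 and 16 without burn day 7 replicates 3, 1 and 2, 3 without sham day 7 replicate 1, 13 without burn day 2 replicate 1 and 16 without sham day 2 replicate 3. Between sham days the count moved by over 1.5 times in 15 of 18 such fits. For a differing effect, where the main count was 0, 10 of 18 such fits called at least 1 row. An arm left with 2 arrays was assumed to vary like the others.

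Whether equal replicate numbers mark pairs was not tested. The correlations of paired deviations ran from -0.0401 to 0.167, 3 of 12 over 0.1, and 7 of 12 sham arrays correlated best with their own number. As a replicate block within days the numbers gave 1 call on day 7, 11 on the mean and 1 for a differing effect. As a replicate block over the series they gave 5 on day 7 and 27 on the mean.

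Of 38 results for single rows, 0 of 431 values under other settings and 0 of 612 with an array left out changed direction, while 124 and 194 no longer passed the threshold and 30 and 0 newly passed it. These rows were selected from the same arrays for their size or direction, so the lack of reversals tests little. The correlation of the effects of days 2 and 7 ran from 0.139 without sham day 2 replicate 1 to 0.421 with the ratio covariate. The level difference of Hk1 ran from -0.0558 without sham day 2 replicate 2, a change of sign, to 0.207 without sham day 2 replicate 1. With an array left out, the level difference of Actb ran from 0.026 to 0.108 (without sham day 7 replicates 3 and 2), that of Gapdh from 0.0223 to 0.0695 (replicates 1 and 2 of the same group), the Gapdh ratio from -0.207 to -0.112 (replicates 2 and 3) and the Hk1 ratio from -0.382 without burn day 7 replicate 1 to -0.0375 without sham day 2 replicate 3. The planned gene list tests and their alternatives were not run because names and values did not match. The mean of the 4 days was not run.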

Other observations

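Of the tests here, those of the row order, of the intensity trend, of the splits for days 2 and 7, of the covariate with permuted ratios and of the splits at an unadjusted p for an effect that differs between days were chosen after the results were seen. The first pattern is the missing correlation between day 1 and the later days. A biological difference between day 1 and later days would leave the bacterial spike controls, which hold no liver RNA, at their levels. The 27 control rows compared by name correlated at -0.152. They include rows of Gapdh, Actb and Hk1, which are rat transcripts, and the spike controls were not compared alone. The same control pattern stood in the first rows of day 1 with a correlation of 0.997, while 15810 other starting rows gave at most 0.640. A candidate explanation is that the values were joined to the names in another row order on day 1. Which order that was, and which order the other 18 arrays have, stays open.

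The next pattern is that day 1 had 0 calls alone and 724 in the fit of all arrays. Shuffling the rows of the other 18 arrays before that fit left a median of 681 calls (649 to 745 in 20 shuffles), so the added calls did not need matching transcripts. A candidate source is spread borrowed from unrelated rows: called rows had a median SD of 0.18 on the other days, against 0.27 for the rest, and of 0.30 on day 1 for both. Of the 10 splits of the 6 arrays, 1, the real one, reached 724, and another split called 328 rows. With 10 splits no share under 0.05 can be had.

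The third pattern is the correlation of 0.187 between the burn effects of days 2 and 7, which is 1 of 3 pairs of days compared. Of 100 pairs of splits of both days, 1, the real one, was as large (highest other 0.166). A chance split of these arrays is argued against, but not chance between animals. Removing an intensity trend left 0.188 and moved no pair of days, so it tested little and that explanation stays open. Lower 3' over 5' ratios of Actb and Gapdh on the burn arrays of both days may contribute, although that of Hk1 was 0.37 higher on day 2: row slopes on the Actb ratio within groups correlated at -0.132 with the burn effect of day 2 (permutation p = 0.089) and at -0.105 with that of day 7 (permutation p = 0.156). These have the sign that RNA quality would give and did not pass the test. With the ratio as covariate the correlation rose to 0.421, but ratios permuted within groups, which keeps the group means, gave a median of 0.468 (95% from 0.414 to 0.548), so this rise decides nothing. RNA quality cannot be told apart from burn here. A shared response to burn on both days stays open and untested.

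Other splits of the arrays were counted for each comparison. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. A real count of 0 is reached by any split. On day 1 all 10 splits reached the real count of 0 calls (highest other 0), on day 2 all 10 (real 0, highest other 5) and on day 4 all 10 (real 0, highest other 1). On day 7 only 1, the real one, reached 8 (highest other 1). For rows at an unadjusted p under 0.05, 1 of 10 splits, the real one, was as large on each day. The real counts were 1778, 1400, 1482 and 1563, and the highest others 1146, 1281, 1304 and 1187. For the mean of days 2, 4 and 7, 1 of 100 splits, the real one, reached 34 calls (highest other 2). This argues against a chance split of these arrays. Splits of arrays cannot speak to chance between animals, since the labels do not say whether arrays came from separate animals. With the Actb ratio as a covariate, 0 rows were called on the mean. For a burn effect that differs between days the real count was 0, which all 100 splits reach by construction (highest other 3), so that count tests nothing. At an unadjusted p under 0.05, 1 of the 100, the real one, reached 1499 rows (highest other 1339). These splits also remove a burn effect that is equal on all days, so they cannot tell whether the effect differed between days. For sham days 1 of 100, the real one, reached 8 (highest other 7). By calls, a chance split of these arrays is argued against only by a margin of 1 row, and leaving out single arrays moved the count from 1 to 25. At an unadjusted p under 0.05, 1 of the 100, the real one, reached 2474 rows (highest other 2056, median of the others 930). By that measure, for which no prediction was written, the sham days stood further apart than in the other splits. The cause was not tested.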
